A study of Mus musculus with 21 samples.

How the data were processed

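The series holds bulk RNA-seq of homogenised mouse placentas at embryonic day 15.5. Klrc1 encodes NKG2A, an inhibitory receptor of natural killer (NK) cells. Per the labels, the 2 groups are reciprocal crosses: Klrc1-KO dams mated with C57BL/6 sires and C57BL/6 dams mated with Klrc1-KO sires, so that fetuses carry 1 mutant copy in both groups and the dams differ. Per the series design text, the fetuses chosen were those nearest to the mean weight of their litter. The labels give 10 placentas per dam group, 5 per group in each of 2 sequencing runs, run 40536 of 2019 and run 40645 of 2020. The second run is labelled as stored frozen, so run and storage cannot be separated. A repeat library of placenta 1 in the second run makes 21 libraries in the labels. The deposited table has 20 sample columns, and a column of the repeat library was not analysed here. Placentas 1 to 10 come from Klrc1-KO dams and placentas 11 to 20 from C57BL/6 dams. The labels do not say which placentas share a dam or litter, so p-values measure the spread between these samples.

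Per the labels' protocols, RNA was extracted with an RNeasy Plus Universal kit, and polyadenylated RNA libraries were made with a TruSeq stranded kit and sequenced on an Illumina NextSeq. The genome build GRCm38 and edgeR are named in the submitters' processing notes. The aligner, the counting tool, the annotation and the filter on low genes are not given in the sources used here. The series design text names a batch correction over the 2 runs.

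The deposited sample columns hold log2 values, which the authors made as log2 counts per 1e6 reads (CPM) with a prior. This was read from the values. Their floor was -3.83 log2 CPM, or 0.0701 CPM, reached only in columns with a gene without reads. With that floor taken for every column, 100% of the 211220 values were whole multiples of 1 read of their library above it, within 0.05 reads. The recovered whole reads show that the columns are scaled to the library but not corrected for run. Per the file headers, the deposited table also gives the authors' own comparison as a log2 fold change, an average log2 CPM, a likelihood ratio score, and a p-value with its adjusted value. No column of per-sample values was left unmapped (0 columns).

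The table lists 10561 genes, of which 10558 were found by identifier in GENCODE M21, an annotation of GRCm38. The symbols of 16 genes had been turned into dates and were replaced from GENCODE. Transcript length and GC content were available for 10554 genes. Reads counted in the listed genes ranged from 18.8 to 40.6 M (1e6 reads) per library. Such depth makes counting error small beside the spread between placentas for most genes. No pair of libraries agreed within counting noise, the lowest chi-square per gene between any 2 libraries being 20.1.

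The design fixed before the data were examined assumed counts. Because the deposited unit was log2 CPM, limma 3.58.1 (R 4.3.3, lmFit and eBayes with a trend) was fitted to the deposited values in place of a count model. The recovered reads entered limma-voom as an alternative, and count models were not used because the file holds log2 values. No further pseudocount was added, since the values already hold a prior. The model had terms for dam and run, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Further fits tested the run term, the interaction of dam and run, and the dam difference within each run. Fold changes are on the log2 CPM scale, Klrc1-KO over C57BL/6 dams, with standard errors from limma.

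The named genes followed a rule fixed in advance. It took the 12 genes with the largest absolute log2 fold change per direction among those passing the threshold, with a mean log2 CPM of at least 0 and no predicted-gene symbol. It added Klrc1, Klrd1, Klrk1, Ncr1 and H2-T23, up to 4 members of each fixed gene list by smallest p, and 5 genes per direction for the run and interaction fits. Of 37 gene lists fixed in advance, 35 had at least 3 measured genes and were tested with limma's camera at a preset correlation between genes of 0.01. The tests were repeated with an estimated correlation and with fry.

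Alternatives fixed before the data were examined were relative log expression and upper quartile scaling, pseudocounts of 0.5, 1 and 2, and leaving out the run term. Covariates for the Y-linked and the decidual stroma means, each run alone, and leaving out each placenta were also fixed then. Scaling and pseudocounts were applied to the recovered reads once the file was seen to hold log2 values. At that point limma-voom on those reads took the place of planned count tools. Alternatives chosen after seeing the data were a per-library natural spline of gene deviations on GC content (5 degrees of freedom, "GC spline"), the same with transcript length, placenta 1 placed in the second run, and fits without placentas 6, 10 and 12 or without placenta 1 as well. Also added were 2 residual principal components in place of the run term, a minimum mean CPM of 10, a yolk sac covariate and exact permutation of list means. Residual components are unrelated to the dam term by construction, so they can lower the spread but not change the dam fold changes. The median log2 fold change over all genes was -0.0052 with the run term and with these components. The 7 genes without a GC value, Vamp7 among them, were left as deposited by the spline.

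The fit was tested on simulated data for 10561 genes, drawn as Poisson reads from the means and library sizes of these samples, with 200 genes changed between 10 and 10 placentas. It recovered 56% of 50 genes changed 1.25-fold, 82% at 1.5-fold, 96% at 2-fold and 100% at 3-fold, with 11 false calls. The spread between simulated placentas was capped at 0.5 log2 units, so these shares are too high for the most variable genes. Simulated genes also varied independently of one another, so structure shared between genes was absent. The 11 false calls therefore give no false-call rate for the real samples. Permutation tests, splits and figures used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.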

Results

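Placental transcripts were measured in 10 placentas of Klrc1-KO dams and 10 of C57BL/6 dams at E15.5, per the labels. The comparison asks how the absence of the maternal receptor NKG2A relates to gene expression in placentas of matched fetal genotype. The recovered read totals were 31.6 to 40.6 M in run 40536, apart from placenta 1 with 23.4 M, and 18.8 to 23.1 M in run 40645 (M, 1e6 reads). Values are log2 CPM, given as mean ± SD over 10 placentas per dam group unless stated otherwise.

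The targeted gene, Klrc1 (GRCm38 chromosome 6, 129666015 to 129678973, minus strand), was not analysed here, and neither were its partner gene Klrd1 and the NK receptor genes Klrk1 and Ncr1. The maternal genotype was therefore not checked from expression. H2-T23, which encodes the Qa-1 ligand of NKG2A, was at 4.98 ± 0.35 in placentas of Klrc1-KO dams and 4.93 ± 0.51 in those of C57BL/6 dams. Its log2 fold change was 0.05 ± 0.18 (SE), with an adjusted p of 0.92 in limma.

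The genes with the largest differences upward in Klrc1-KO dams had varied functions. Prap1, a secreted proline-rich acidic protein of uterine and gut epithelium, had the largest difference, at 3.98 ± 0.76 against 2.35 ± 1.28, or 3.10-fold (log2 fold change 1.63 ± 0.45 SE, adjusted p = 0.034). The call of Prap1 was lost in 8 of 20 fits without 1 placenta (highest adjusted p 0.069 in limma) and with the yolk sac covariate. Cts6, a cathepsin of the placental cluster on chromosome 13, was 1.77-fold higher (11.57 ± 0.43 against 10.75 ± 0.51, adjusted p = 0.021). The non-coding RNA Bc1 was 1.88-fold higher, and Snhg3, a host gene of small nucleolar RNAs, had a log2 fold change of 0.59 ± 0.13 (SE). Mgst1, a microsomal glutathione S-transferase, was at 5.04 ± 0.63 against 4.37 ± 0.42. The remaining genes of this group were Ap1s2, Vamp7 and Chml of vesicle traffic, the zinc finger genes Zfp931, Zfp758 and Zfp953, and the Gt(ROSA)26Sor transcript, with log2 fold changes from 0.61 to 0.72. Zinc finger genes of these clusters resemble one another closely, so reads may have been divided between copies and their values are uncertain.

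Genes lower in placentas of Klrc1-KO dams differed by smaller amounts. Lrrn4 fell to 0.598 of its level in C57BL/6 dams (2.48 ± 0.44 against 3.22 ± 0.48, adjusted p = 0.029). Hmox1, the stress-induced heme oxygenase, had a log2 fold change of -0.42 ± 0.11 (SE, adjusted p = 0.025), and Ldlr, the low density lipoprotein receptor, one of -0.41 ± 0.10 (SE, adjusted p = 0.021). Mvp, the major vault protein, was at 6.91 ± 0.22 against 7.31 ± 0.20 (adjusted p = 0.0058). Lmna, which encodes lamins A and C, and Parp1, a DNA repair enzyme, had log2 fold changes of -0.34 and -0.33. Cdh3, which encodes P-cadherin, and Tgm2, a transglutaminase, were lower by similar amounts, at -0.34 and -0.33. The other genes of this group were Atp2c2 (-0.57), Unc5a (-0.45), Ldoc1 (-0.43) and Rnf157 (-0.35).

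**Figure D1:**
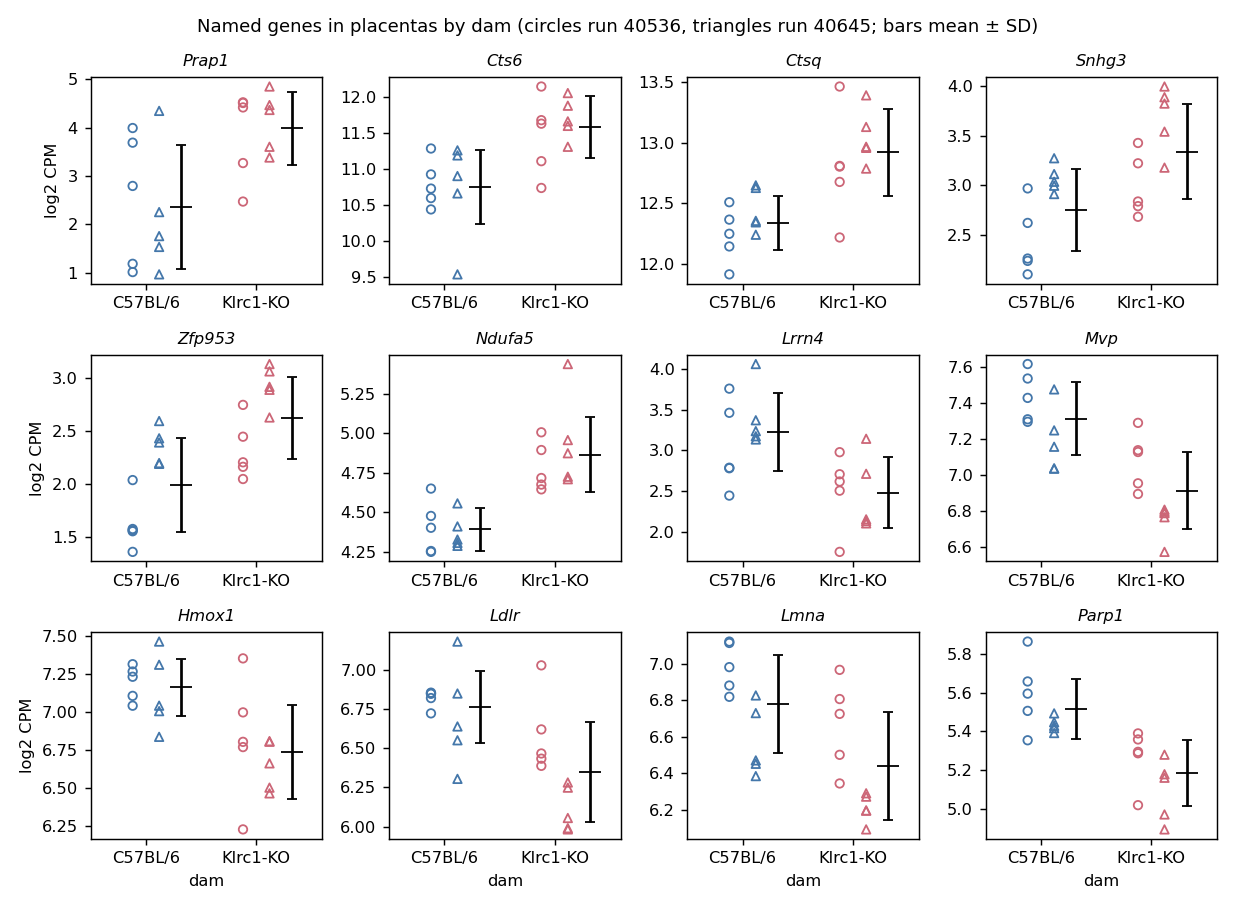
Expression of 12 named genes in each placenta, in log2 CPM, by dam (C57BL/6 in blue, Klrc1-KO in red), with circles for run 40536, triangles for run 40645 and black bars for the mean ± SD of 10 placentas. Prap1 was at 3.98 ± 0.76 in Klrc1-KO dams and 2.35 ± 1.28 in C57BL/6 dams, while Mvp was at 6.91 ± 0.22 and 7.31 ± 0.20.

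Across all 10561 genes, limma called 710 genes between the dam groups, 531 higher and 179 lower in Klrc1-KO dams. The median log2 fold change was 0.31 among genes called higher and -0.22 among those called lower, and only Prap1 exceeded an absolute value of 1. All 710 had the same sign in both runs, which their selection on the dam difference over both runs favours. Genes of low GC content predominated among those called higher, with a median GC content of 41.4% against 52.8% among those called lower and 49.6% over all genes. Across genes, which are not independent replicates, the fold change and GC content had a Spearman rho of -0.51. After the GC spline, limma called 106 genes, 88 of them among the 710 with the same sign. Without the run term, 20 genes were called, none of them among the 24 named above. Of the 24 genes named above, Zfp953, Snhg3, Mvp, Lmna and Parp1 kept their call after the GC spline, and all 24 kept their sign. The other 19 had adjusted p-values above 0.05 after the spline, such as 0.065 for Prap1, 0.12 for Cts6 and 0.081 for Hmox1. The log2 fold changes of these 3 genes after the spline were 1.69, 0.68 and -0.36, against 1.63, 0.83 and -0.42 before. Others shrank more, such as Zfp931 from 0.72 to 0.32, Zfp758 from 0.68 to 0.35, Ap1s2 from 0.63 to 0.30 and Gt(ROSA)26Sor from 0.62 to 0.34.

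**Figure D2:**
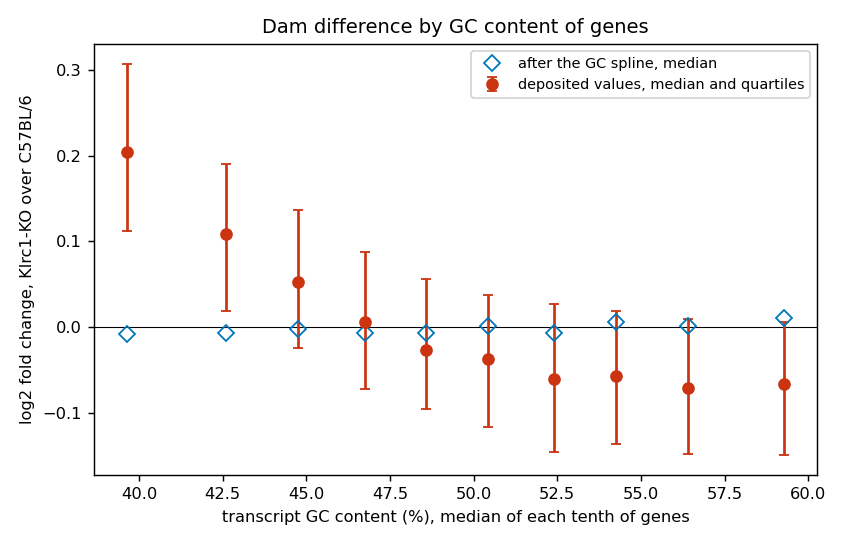
Dam difference by transcript GC content, with genes divided into 10 groups of equal size: the horizontal axis gives the median GC percent of each group and the vertical axis the log2 fold change, Klrc1-KO over C57BL/6 dams. Red points and bars are the median and quartiles from deposited values, running from 0.20 in the group of lowest GC to -0.07 in the highest, and blue diamonds are medians after the GC spline.

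Within run 40536, limma called 0 genes between 5 and 5 placentas at the adjusted threshold, with 916 at an unadjusted p under 0.05, and limma-voom also called 0. Within run 40645 both tools again called 0 genes, with 1491 at an unadjusted p under 0.05 in limma. The interaction of dam and run, which asks whether the dam difference differed between runs, had 0 calls in limma and limma-voom, with 67 genes at an unadjusted p under 0.05 in limma. The single-run fits had 10 placentas in place of 20, and lower power by construction.

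At the preset correlation 4 lists passed the list test, while random regroupings of placentas within runs passed a median of 11. The placental cathepsins, proteases of trophoblast giant cells and related cells, passed upward at that correlation (camera adjusted p = 0.014). With an estimated correlation their adjusted p was 0.13. Of 8 measured members, 4 were called higher over all genes and 4 when adjusted over the list alone, and none was lower. Ctsq was at 12.92 ± 0.36 against 12.34 ± 0.22, Ctsj at 13.82 ± 0.21 against 13.42 ± 0.13, and Ctsr at 10.28 ± 0.18 against 9.95 ± 0.24. The list median was 0.27 on the log2 scale. Exact permutation of the list mean gave p = 0.021 (0.25 adjusted over the lists), and p = 0.072 after the GC spline. With fry, which asks whether the list moves on balance one way, the adjusted p was 0.00055, and after the GC spline the camera adjusted p was 0.11. None of the 4 genes was called after the spline, with log2 fold changes of 0.68 for Cts6, 0.43 for Ctsq, 0.31 for Ctsj and 0.24 for Ctsr. Only Ctsq was called without placentas 1, 6, 10 and 12. In that fit Cts6 had a log2 fold change of 0.71, against 0.83 with all placentas. The list's camera adjusted p was 0.0025 there at the preset correlation. These genes are close paralogs in 1 cluster, so reads may have been divided between copies.

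Nuclear genes of oxidative phosphorylation passed the list test upward at the preset correlation (camera adjusted p = 0.017), but the adjusted p was 0.87 with an estimated correlation. The difference of the list mean between dams was 0.11 (exact permutation p = 0.052), and 0.06 (p = 0.10 by the same permutation) without placenta 10, whose list mean of 6.66 stood apart from the others. Of 37 measured members, 8 were called higher (11 adjusted over the list alone) and none lower. The complex I subunit Ndufa5 was at 4.86 ± 0.24 against 4.39 ± 0.13, with a log2 fold change of 0.47 ± 0.09 (SE, adjusted p = 0.0067). Cox6c and Cox7a2, subunits of cytochrome c oxidase, each had a log2 fold change of 0.44, and all 3 genes kept their call after the GC spline. Ndufv2 had a log2 fold change of 0.35 and an adjusted p of 0.26 after the spline. After the GC spline the list's camera adjusted p was 0.00095, but the adjusted p was 0.98 with an estimated correlation, and exact permutation of the list mean gave p = 0.071, and p = 0.14 without placenta 10.

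Mitochondrially encoded genes formed the list with the smallest camera adjusted p, 0.0023, but the adjusted p was 0.87 with an estimated correlation. All 9 measured members had a positive sign. The ribosomal RNAs mt-Rnr2 and mt-Rnr1 were called higher, with log2 fold changes of 0.50 ± 0.12 and 0.36 ± 0.10 (SE), and 7 members passed when adjusted over the list alone. These transcripts are low in GC content, and the list median went from 0.29 to 0.02 after the GC spline. Exact permutation of the list mean gave p = 0.0084 (0.15 adjusted over the lists) before the spline and p = 0.69 after it.

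Cholesterol and steroid synthesis genes had a list median of -0.13 and a camera adjusted p of 0.044 at the preset correlation, but the adjusted p was 0.87 with an estimated correlation. Exact permutation of the list mean gave p = 0.13. Of 25 measured genes only Ldlr was called (also over the list alone), and it takes up lipoprotein rather than making sterol. Srebf2, a transcription factor of sterol synthesis, had a log2 fold change of -0.38 ± 0.12 (SE, adjusted p = 0.064). After the GC spline the camera adjusted p of the list was 0.10. The difference of the list mean was -0.10 both before and after, while the list median went from -0.13 to -0.08 and Ldlr from -0.41 to -0.35. These values do not settle whether the lost call followed GC content.

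Other trophoblast lists did not pass the list test with all placentas. Among trophoblast giant cell markers, 4 of 22 measured genes were higher (4 over the list alone), the cathepsins already named. In the prolactin family, 2 of 23 were called higher (2 over the list alone), Prl2b1 at 13.52 ± 0.49 against 12.95 ± 0.46 and Prl3c1 at 6.82 ± 0.49 against 6.36 ± 0.52. Both also belong to the 33 measured junctional zone and glycogen trophoblast markers, where the glycogen synthase Gys1 was called lower (-0.26). That list had a camera adjusted p of 0.28. After the GC spline Prl2b1 (0.40, adjusted p = 0.091), Prl3c1 (0.24, adjusted p = 0.30) and Gys1 (-0.19, adjusted p = 0.073) were not called. Of 23 pregnancy-specific glycoprotein and Ceacam genes, limma called 0, with a median of -0.32. Ceacam9, a member of that list, had an adjusted p of 0.12 in limma, against 0.043 in the authors' deposited likelihood ratio comparison. Of 25 labyrinth syncytiotrophoblast markers, Cdh3 was the single call.

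Immune lists showed few differences. Of 28 listed NK and cytotoxic lymphocyte markers, 4 were measured. None of the 4 passed, with Il2rb at a log2 fold change of -0.45 ± 0.19 (SE, adjusted p = 0.17). None of 7 granzyme and perforin genes passed either, and Gzme had a log2 fold change of 0.21 ± 0.31 (SE). The SE was 0.49 for Gzmd and Gzmf and 0.42 for Prf1, against 0.19 for Gzmm. Large differences in such genes could be missed, so these values do not show that NK cells were alike between the dam groups. In the NK gene complex region of chromosome 6, 8 genes were measured and Magohb, an exon junction factor, was called higher (0.40 ± 0.10 SE), but not after the GC spline (0.28, adjusted p = 0.16). Of 31 interferon response genes, Rtp4 was called higher (0.27 ± 0.07 SE), also after the GC spline. The 18 genes of MHC class I and antigen processing, 10 macrophage markers and 3 neutrophil markers had 0 calls. T and B cell markers had 0 measured genes in the table used.

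Of 25 endothelial markers, Cdh5, which encodes VE-cadherin, was called lower (8.72 ± 0.28 against 9.02 ± 0.12), and 0 passed over the list alone. The 36 angiogenic and vascular factors had 0 calls. Among 35 hypoxia response genes, the glycolytic genes Pgam1 (-0.17), Aldoa (-0.17) and Hk1 (-0.29) were called lower and Bnip3l, a mitophagy receptor, higher (0.29). In all, 4 members were lower and 1 higher, or 5 and 1 over the list alone, and the camera adjusted p was 0.063. Of 57 imprinted genes, Impact (0.25) and Mcts2 (0.31) were called higher and Gab1 (-0.16) lower. After the GC spline none of these genes was called. The log2 fold changes of Mcts2 (0.30) and Cdh5 (-0.25) stayed close to those before, while those of Impact (0.13), Bnip3l (0.16) and Aldoa (-0.09) shrank.

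The remaining lists had 0 called genes over all genes tested: decidual stroma, smooth muscle, uterine epithelium, erythroid, yolk sac endoderm, nutrient transporters, growth factor and IGF axis, TGF-beta and BMP signalling, Wnt signalling, extracellular matrix, complement and coagulation, cell cycle, unfolded protein response, immediate early and heat shock genes, and Y-linked genes. Over the list alone, 2 uterine epithelium markers passed, the lowest p-values being those of Krt19 (-0.22 ± 0.07 SE) and Krt18 (-0.29 ± 0.09 SE). The growth factor and IGF axis list had a difference of the list mean of -0.11 (exact permutation p = 0.0083, 0.15 adjusted over the lists). After the GC spline the difference was -0.07 (exact permutation p = 0.042, 0.84 adjusted). Xist, the single X-inactivation transcript, had a log2 fold change of -0.04 ± 1.55 (SE).

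**Figure D3:**
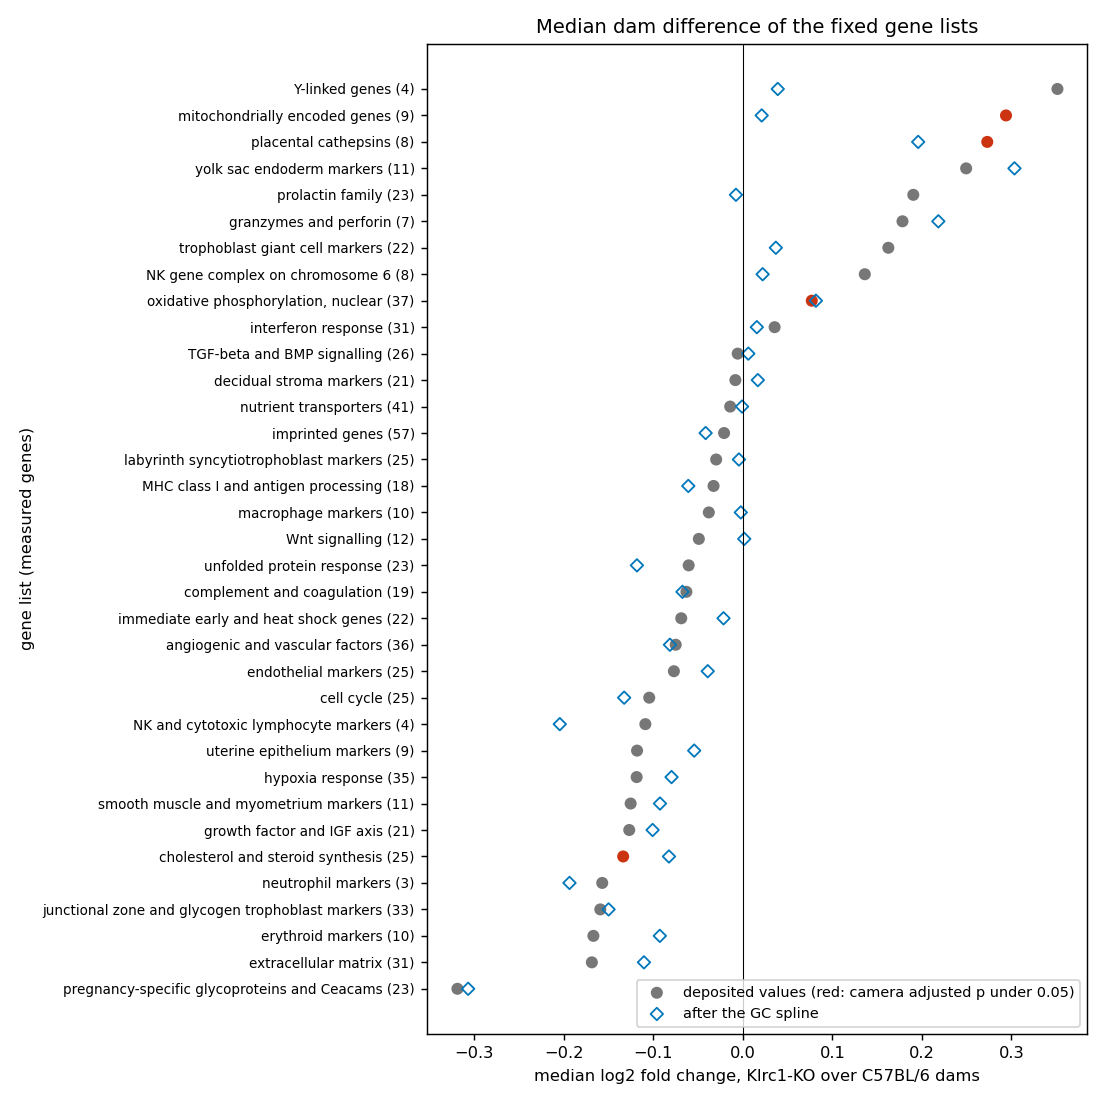
Median log2 fold change of each of 35 gene lists, Klrc1-KO over C57BL/6 dams, with the number of measured genes in brackets. Filled circles are deposited values, red for the 4 lists with a camera adjusted p under 0.05, and open diamonds are medians after the GC spline, where the median of mitochondrially encoded genes was 0.02.

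Transcripts of maternal decidua and of yolk sac endoderm varied widely between placentas. Prl8a2, a prolactin-family gene of decidua, was at 1.06 in placenta 12, 1.97 in placenta 6 and 2.51 in placenta 10, and at 6.28 or more in the others. Afp, an abundant transcript of yolk sac endoderm, was at 13.82 in placenta 10 and 11.41 in placenta 9. Without placentas 6, 10 and 12 and without placenta 1, limma called 237 genes, 217 of them among the 710, and 2 genes with the GC spline added. In the former fit Mvp, Parp1 and Ndufa5 kept their calls. Of the 24 named genes, 17 were not called with these 16 placentas. Some of these kept most of their log2 fold change, such as Prap1 (1.70), Cts6 (0.71) and Ldlr (-0.38). Others shrank, such as Mgst1 from 0.68 to 0.40, Ap1s2 from 0.63 to 0.38 and Atp2c2 from -0.57 to -0.37.

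**Figure D4:**
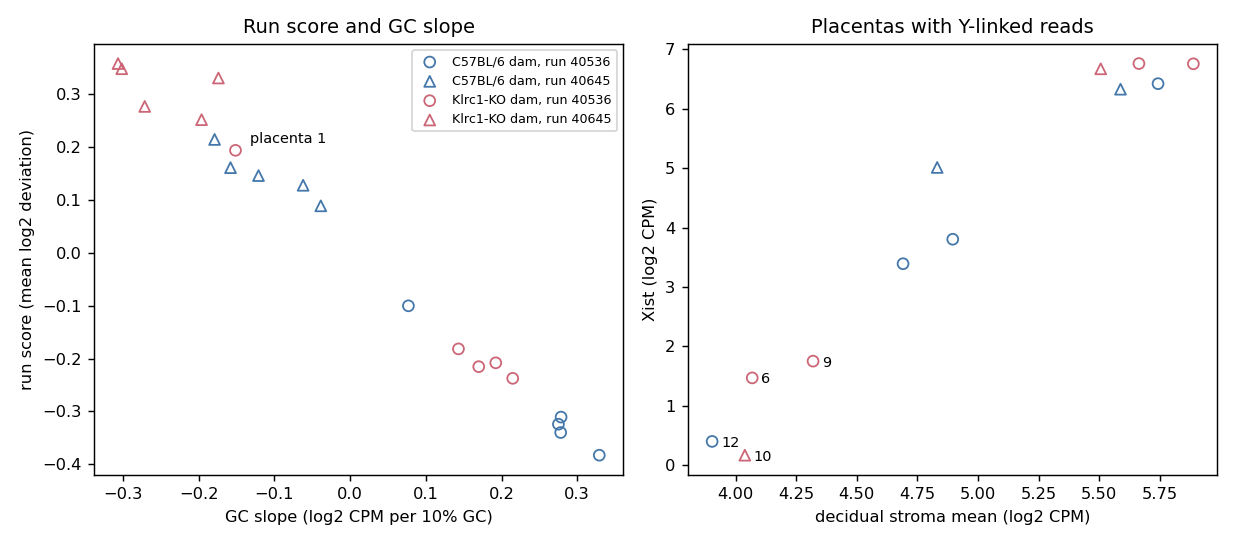
Left, the run score of each placenta (mean log2 deviation over 1905 genes) against its GC slope in log2 CPM per 10% GC, with placenta 1 at a run score of 0.19. Right, Xist against the decidual stroma mean, both in log2 CPM, in the 12 placentas with Y-linked reads (C57BL/6 dams in blue, Klrc1-KO dams in red; circles run 40536, triangles run 40645).

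The authors' deposited table listed 19 genes at an adjusted p under 0.05, 15 higher and 4 lower in Klrc1-KO dams. Among the higher genes, the log2 fold changes in the authors' deposited table were 0.46 for Rpl22 and 0.45 for Rps27, which encode ribosomal proteins, and 0.37 for Chchd1, which encodes a mitochondrial protein. The lower genes of the authors' deposited table were Ldoc1 (-0.53), Atic (-0.36), Lrrn4 (-0.77) and Ceacam9 (-0.71). Of the 19 genes of the authors' deposited table, limma called 18 with the same sign, and 10 after the GC spline. Of the 710 genes, 707 had the same sign in the authors' deposited table. Across all genes, which are not independent replicates, the fold changes of limma and of the authors' deposited table had a Pearson r of 0.72. The authors' deposited fold changes had almost no trend with GC content (Spearman rho -0.05 across genes, against -0.51 in limma), for a reason not tested here.

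The 2 sequencing runs differed more than the dam groups. limma called 4291 genes between runs, 2216 higher and 2075 lower in run 40645. Snhg14, a long non-coding RNA, was at a mean of 5.15 in run 40645 and 3.56 in run 40536 (log2 fold change 1.59 ± 0.25 SE, adjusted p = 8.25e-05), and Zxdb was at 4.66 against 3.17. Gt(ROSA)26Sor, Arxes2 and Zfp994 were the other genes with the largest differences upward. The 5.8S ribosomal RNA n-R5-8s1 was lower in run 40645 (-2.16 ± 0.55 SE), as were CAAA01147332.1, Scand1, Mir6236 and Plec, the cytolinker plectin (-0.81). The run difference followed GC content across genes (Spearman rho -0.83), and 805 genes were called after the GC spline, 497 of them among the 4291. Storage went with run in the labels. Fetal sex was uneven between runs, with 4 of the 12 placentas with Y-linked reads in run 40645, and the run fit had no sex covariate.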

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

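The tests in this part were chosen after the results were seen. Among 120 groups of 10 placentas (60 measures in 2 dam groups), 9 had an extreme placenta standing apart from the rest, where chance gives about 1 in 20 groups. Placenta 10 of the Klrc1-KO dams accounted for 5 of them. It had the lowest slope of expression on transcript length (-0.25, nearest other -0.04), the highest mean of nuclear oxidative phosphorylation genes (6.66, nearest other 6.22), and the highest Bc1 (5.97), Mgst1 (6.57) and Chml (4.79). Placenta 6 had the lowest mean of pregnancy-specific glycoproteins and Ceacams (8.22, nearest other 9.67), and placenta 4 the highest mean of immediate early and heat shock genes (6.05). Among C57BL/6 dams, placenta 11 had the lowest Cts6 (9.53, nearest other 10.43) and placenta 17 the lowest Rnf157 (4.34). No biological explanation of these single placentas was tested.

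The first pattern is that genes of low GC content were higher in placentas of Klrc1-KO dams (Spearman rho of fold change and GC content -0.51 across genes, against -0.05 for the authors' deposited fold changes). The GC slope, in log2 CPM per 10% GC, differed by -0.14 between dams within runs (exact permutation p = 0.0031), and by -0.10 without placenta 1 (exact permutation p = 0.0069), which argues against library-to-library bias unrelated to the dam. The 88 calls that remained after the spline do not rest on the GC trend that the spline removed. GC bias of another form is not excluded for them, since the other splits, with at most 0 calls there, test only the regrouping of placentas. With placentas 1, 6, 10 and 12 also left out, 2 genes were called with the spline. For the 622 calls that were lost, the median ratio of the fold change after over before was 0.59, with a ratio under 0.5 in 239 genes and of 0.8 or more in 108, and Prap1 went from 1.63 to 1.69. For genes whose folds shrank, GC bias and dam genotype cannot be told apart, because a preparation order that followed the dam would give the same values, while removing the GC trend left the folds of the 108 largely in place.

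The second pattern is that placenta 1, labelled as run 40536, had the profile of the other run. Its run score, the mean log2 deviation over 1905 genes that separated the runs without it, was 0.19, inside the range of run 40645 (0.09 to 0.36) and outside that of the other placentas of run 40536 (-0.38 to -0.10). Fewer reads do not account for this, since the other 9 libraries of that run, thinned to 23.4 M (1e6) reads, reached at most -0.10. A candidate explanation is that the column holds a library of run 40645, such as the repeat library named in the labels, which is in keeping with its score of 0.19. With placenta 1 placed in run 40645, limma called 514 genes between dams, 507 of them among the 710.

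The third pattern is the several-fold difference in decidual and yolk sac transcripts between placentas of one dam group. Over the 12 placentas with Y-linked reads, whose fetal cells should lack Xist, Xist correlated with the decidual stroma mean (Pearson r = 0.98, permutation p = 1e-05, the smallest that 100000 resamples can give; Spearman rho = 0.94, p = 3e-05). It held without placentas 8 and 12 (r = 0.97, permutation p = 0.00011) and within run 40536 (r = 0.99, n = 8, exact permutation p = 9.92e-05), and run 40645 had 4 such placentas, too few for a value. Differing amounts of maternal decidua may therefore be the source of the variation in decidual transcripts. The decidual mean differed by -0.06 between dams (exact permutation within runs, p = 0.87), which argues against a dam difference in its amount as the source of the dam calls. All 710 remained with that mean as a covariate, but a covariate so alike between dams could hardly remove calls. Without placentas 6, 10 and 12, and so with fewer placentas, 385 of the 710 were called. Other differences in tissue make-up are not excluded. The yolk sac transcripts, whose list mean was 8.73 in placenta 10 and 4.12 in placenta 12 at similarly low decidual means of 4.04 and 3.90, were not tested for a source.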

How the results depend on the processing

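Alternatives chosen after seeing the data are GC splines, placement of placenta 1, fits without named placentas, residual components, CPM minimum, yolk sac covariate and permutation of list means. Recovered reads, with limma-voom, followed once the file was seen to hold log2 values. The 710 dam calls became 20 without the run term, 1189 with the decidual covariate, 106 with the GC spline and 106 with the GC and length spline. They became 466 without placentas 6, 10 and 12, 237 without placenta 1 as well, and 2 with the GC spline in that set. The 2172 with 2 residual components reflect lower spread, not larger folds. Each run alone gave 0 and 0, with 10 placentas in place of 20. Scaling, limma-voom, pseudocounts, the Y-linked and yolk sac covariates and the CPM minimum of 10 gave 606 to 743, and placenta 1 placed in run 40645 gave 514. Leaving out 1 placenta gave 404 to 1032, with 472 without placenta 1, 404 without 2, 419 without 16, 410 without 19 and 425 without 20. The 4291 run calls became 805 with the GC spline, 906 with the GC and length spline and 1249 with the GC spline without placentas 1, 6, 10 and 12. They became 4707 with placenta 1 placed in run 40645, and ranged from 3893 to 4753 without 1 placenta. The interaction and the single-run fits had 0 calls under every alternative run, including each placenta left out (0 to 0).

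The 4 gene lists became 0 with an estimated correlation, 1 with fry, 0 by exact permutation of list means with and 0 without the GC spline, 1 with the GC spline and 2 with the GC and length spline. They became 7 with limma-voom, 9 without the run term, 9 without placentas 6, 10 and 12, 13 without placenta 1 as well, 8 with the GC spline in that set and 8 in run 40536 alone. Without 1 placenta the number was 3 to 10, with 7 without placenta 1, 2 or 12 and 10 without placenta 6. Of the 4 lists, the placental cathepsins (camera adjusted p = 0.0025) and cholesterol and steroid synthesis (0.0061) were among the 13 without placentas 1, 6, 10 and 12. Mitochondrially encoded genes (0.079) and nuclear oxidative phosphorylation (0.089) were not. The cause of these changes was not tested.

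Of the 24 named genes, 11 kept their call whichever placenta was left out and 13 lost it without at least 1, the highest adjusted p being 0.094 (Unc5a without placenta 20). Over the 154 genes followed and all alternatives, 1 called value changed sign, mt-Rnr1 with the GC and length spline (-0.11). Over all genes, more genes called in the main or the alternative fit changed sign. They numbered 24 with the GC spline, 32 with the GC and length spline and 21 with the GC spline without placentas 1, 6, 10 and 12. No paired analysis was possible because the replicate numbers are not shared between the dam groups. Not run were the DESeq2 Wald test and surrogate variables (count tools were not used because the file holds log2 values, though reads were recovered), no filter beyond 1 count (the table is already filtered), a mean CPM of 1 (the lowest mean was 4.76, so nothing is removed) and the repeat library (not analysed here).

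Regrouping placentas within runs 100 times gave at most 343 dam calls against 710 (1 split as large, the real one). After the GC spline the regroupings gave at most 0 against 106 (1 split). Regrouping run labels within dam groups gave at most 2659 run calls against 4291 (1 split). Random regrouping of single placentas is thus an unlikely source of these counts. The splits treat placentas as independent, and the labels do not give litters. A litter or preparation shared within a dam group is therefore not excluded. For the 4 lists, random regrouping within runs is not excluded either, since 93 splits gave as many. The other splits passed a median of 11 lists and at most 21. The number of lists passing at the preset correlation is therefore no evidence of a dam difference. For the interaction and the single-run fits the splits decide nothing, because a count of 0 is reached by all 100 splits whatever the data (highest 13, 1061 and 215). A split with 1061 calls points to structure among the placentas of run 40536.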

Other observations

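The tests of location near Klrc1 and on the X chromosome were fixed before their results were seen, and those of ribosomal protein genes were chosen afterwards. Cytosolic ribosomal protein genes had not been among the fixed lists. Of 74 measured, limma called 13 higher and 0 lower in placentas of Klrc1-KO dams, 65 had a positive sign, and the median log2 fold change was 0.14. The largest log2 fold changes were 0.57 for Rpl22l1, 0.49 for Rps27 and 0.48 for Rpl39, named because of their values. Rpl39 was not called after the GC spline (adjusted p = 0.066 in limma), though its log2 fold change was 0.50 there. After the GC spline, 8 were called higher and the median was 0.15, so the group did not follow the GC trend, with a median GC content of 50.8%. Without placentas 1, 6, 10 and 12, 0 of the 13 were called, with adjusted p-values from 0.051 to 0.15 in limma. The log2 fold changes in that fit were 0.45 for Rpl22l1, 0.43 for Rps27 and 0.43 for Rpl39, so most of each difference remained with fewer placentas. Transcripts of the 74 genes are short, with a median of 1108 nt against 3512 nt over all genes.

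A hypothesis from this is that ribosomal protein transcripts may be higher in placentas of Klrc1-KO dams beyond the GC trend. The mean over these genes after the GC spline was higher by 0.18 (exact permutation within runs, two-sided, p = 0.028), against 0.16 (p = 0.061 by the same exact permutation) in the deposited values. With the GC and length spline the difference was 0.08 (exact permutation p = 0.0497), and with the GC spline alone and without placenta 10, the placenta with the extreme length slope, it was 0.13 (exact permutation p = 0.056). The hypothesis stays open, since 1 placenta decides whether the test passes and transcript length remains as an alternative.

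A segment carried along with the mutation was tested as a source of dam calls. Within 10 Mb of Klrc1, 5 of 95 genes were called (5.26%), against 6.74% of the other 10466 genes (Fisher's exact test, two-sided, p = 0.84), and 0 of the 95 after the GC spline. No excess was seen, but the test excludes little, since such a segment would be heterozygous in the fetal cells of both dam groups and would differ only in maternal tissue. The called genes were Mgst1, Ptpn6, Chd4, Magohb and Pex5.

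On the X chromosome, 34 of 359 genes were called (9.47%), against 6.61% of 10181 autosomal genes (Fisher's exact test, two-sided, p = 0.041). The prediction of an excess was met, but X-linked genes had a lower median GC content (45.6% against 49.7%), and after the GC spline the shares were 1.11% and 1.00% (Fisher's exact test, p = 0.78). Parent of origin of the X chromosome and the GC trend cannot be told apart for these genes. Fetal sex was balanced between the dam groups. Y-linked reads were near the floor in 1 of 5 placentas of each dam group in run 40536 and 3 of 5 in run 40645. The balance within runs rests on the labelled run of placenta 1, while over both runs 4 placentas of each dam group had such low reads. With the Y-linked mean as a covariate, 603 of the 710 dam calls remained, but a covariate so balanced could hardly remove calls. The even numbers argue against a difference in sex between the dam groups as the source of the dam calls.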
